A study of Homo sapiens with 6 samples.

How the data were processed

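The series measured RNA of MM1.S, a human multiple myeloma cell line, on 6 Affymetrix arrays of 1 colour. Per the labels' protocols, cells were infected with lentivirus carrying either a control or a beta-catenin shRNA, GFP-positive cells were sorted and grown as triplicate cultures, and total RNA was turned into biotin-labelled cRNA. Group and replicate number were taken from the sample titles, which give 3 control and 3 knockdown arrays. A part of the labels speaks of embryos and maternal transcripts, which contradicts the cell line named in the other labels, and was not used.

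The values deposited by the authors were log2 expression values, 1 per probe set and array. They had a floor at 4, the log2 of 16, which fits values of the form log2(signal + 16); this form was read from the values and is not stated in the labels. The submitters' processing notes name MAS5 and PLIER, a pair of Affymetrix summary methods, without versions and without the role of each. Which method made the deposited log2 values, and how arrays were normalized to each other, is not given in the sources used here. Because of the offset of 16, a fold is on the log2(signal + 16) scale and understates the change of dim probe sets. The 6 array medians lay between 5.44 and 5.54 and so agreed within the allowed gap of 0.1; the values were used as deposited, with no further normalization.

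The table held 54675 probe sets, of which 62 were Affymetrix control probe sets and stayed out of the tests. The values of some of these control probe sets are not reported here. Under the platform annotation given for these probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 had none here. Of those with 1 symbol, 41037 were found by gene ID in a RefSeq gene table of assembly GRCh38.p14, and 0 of these symbols differed from it; that table served for names alone, and no coordinates are given because no genome build is named for the arrays. No gene was named from a probe set with several symbols. A gene was read by 1 probe set, the one with the highest mean over the 6 arrays among those with exactly 1 symbol. A gene was tested if that mean was at or above 5.49, the median of all non-control probe set means. This left 12939 of 19775 genes in the test and 6836 below the filter. The alternative that averaged a gene's probe sets took in all those with 1 symbol, also ones below the filter. A smaller change under that mean therefore need not show that bright probe sets disagree. List members with no probe set of a single symbol were not analysed here.

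Knockdown and control were compared with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Changes are knockdown minus control on the log2 scale, with the standard error of the moderated fit. Where all probe sets of a gene are compared, the adjustment ran over all non-control probe sets. Single values were compared with exact two-sided permutation tests, which with 3 against 3 arrays cannot give a p below 0.1. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists of at least 5 tested members. Camera asks whether a list moved relative to the other genes. It was repeated with the correlation estimated from the arrays, and with fry, which asks whether a list's genes moved on balance in 1 direction. Member counts were made over all genes tested and again adjusted over the list alone.

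The groups, main tests, gene lists, most alternatives and the rule for named genes were chosen before the data were examined. The rule named CTNNB1 with each of its probe sets, AURKA and AURKB; the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, leaving out placeholder symbols; and up to 4 called members of each list by adjusted p. Genes outside the rule are said to be so where they are named. The lists covered Wnt/beta-catenin targets, Wnt pathway components, cadherins and catenins, mitosis, DNA replication, cyclins and CDKs, p53 targets, apoptosis regulators, ribosome biogenesis, the unfolded protein response, ATF4 targets, NF-kB targets, the interferon response, cholesterol biosynthesis, hypoxia and glycolysis, oxidative phosphorylation, the proteasome, heat shock and immediate early genes, plasma cell identity, MAF-type myeloma, and markers of B cells, T and NK cells, myeloid cells, fibroblasts, kidney epithelial packaging cells and erythroid cells.

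Alternatives changed 1 choice at a time: the replicate number as a block, quantile normalization, centring on array medians, cyclic loess, no filter or a filter at the 75th percentile, other probe set rules, other variance models, a test without moderation, a test against a 1.2-fold change, other offsets, and leaving out each array. The offsets of 1 and 64 had been planned for linear values; since the table was on the log2 scale they were run after turning the values back, and these runs and cyclic loess were chosen after seeing the data. The test was tried on simulated data: with 3 against 3 arrays and 12939 genes it recovered 49.3% of genes changed 1.25-fold, 98.5% of those changed 1.5-fold and 100% of those changed 2-fold, with 12 false calls. With no change simulated it called 1 gene. The simulation changed 67, 67 and 66 genes at these folds and drew independent noise for each gene. In the data 47.3% of tested genes were called, so these rates need not hold for them. The number of arrays limits the precision.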

Results

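The data were expression profiles of MM1.S cells, a line grown from a patient's multiple myeloma, a cancer of plasma cells. The cells carried a lentiviral control shRNA or an shRNA against beta-catenin, and GFP-positive cells had been sorted. There were 3 arrays of control cultures and 3 of knockdown cultures. Array medians were 5.44 to 5.50 in the controls and 5.50 to 5.54 in the knockdown. Pearson's r across probe sets, which are not independent replicates, was 0.980 to 0.983 between control arrays, 0.986 to 0.990 between knockdown arrays and 0.945 to 0.954 between groups. The labels describe triplicate cultures of sorted cells and no separate infections. The limma p-values thus rest on the spread between these cultures, which the moderated fit pools in part over genes, and not on spread between infections. The labels used here do not give the shRNA's sequence or the number of hairpins, and off-target effects of the shRNA were not analysed here. The number of arrays limits the precision.

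The first question was whether the targeted transcript was lower. CTNNB1, the gene of beta-catenin, which is a co-activator of Wnt signalling and a part of cadherin junctions, was 7.75 ± 0.08 (SD, n = 3) in control and 6.42 ± 0.10 (SD, n = 3) in knockdown cultures, by the brightest of its 3 probe sets. The fall was −1.33 on the log2 scale (SE 0.10), or 2.51-fold, with 39.8% of the control level left (limma, adjusted p = 9.04e-12). The 3 control arrays read 7.82, 7.67 and 7.75 and the 3 knockdown arrays 6.39, 6.53 and 6.34, which do not overlap (exact permutation p = 0.1, the smallest this design can give). The other CTNNB1 probe sets were not called lower. Both were dimmer in the controls than the brightest one. The first of these was higher in the knockdown by 0.33 (6.06 against 6.39, limma, adjusted p = 0.0390 over all probe sets). The second differed by −0.07 (5.57 against 5.50, limma, adjusted p = 0.716). It lay just above the filter, where the offset understates a change, so it says little about a fall. The fall in the transcript was thus seen by 1 of 3 probe sets, the brightest. The mean over all 3 changed by −0.36 (limma, adjusted p = 0.00162). That mean weighs the dim probe sets like the bright one, so it need not give the size of the fall. Over all settings of the test the adjusted p of CTNNB1 ran from 2.13e-24 to 0.00212. Which parts of the transcript each probe set reads was not analysed here.

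The Aurora kinases, named in advance because work on beta-catenin in myeloma deals with them, were both lower in the knockdown. AURKA, a kinase of centrosomes and spindle assembly, fell from 7.61 ± 0.15 to 5.80 ± 0.16 (SD, n = 3 each) by its brightest probe set, a change of −1.81 (SE 0.11), or 3.51-fold (limma, adjusted p = 7.41e-14). A further AURKA probe set gave −2.09, and a dim one below the filter gave −0.29. AURKB, the kinase of the chromosomal passenger complex, fell from 8.08 ± 0.12 to 6.02 ± 0.14 (SD, n = 3 each) by its brightest probe set, a change of −2.06 (SE 0.11), or 4.17-fold (limma, adjusted p = 1.18e-15). Its other probe set gave −1.28.

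**Figure D1:**
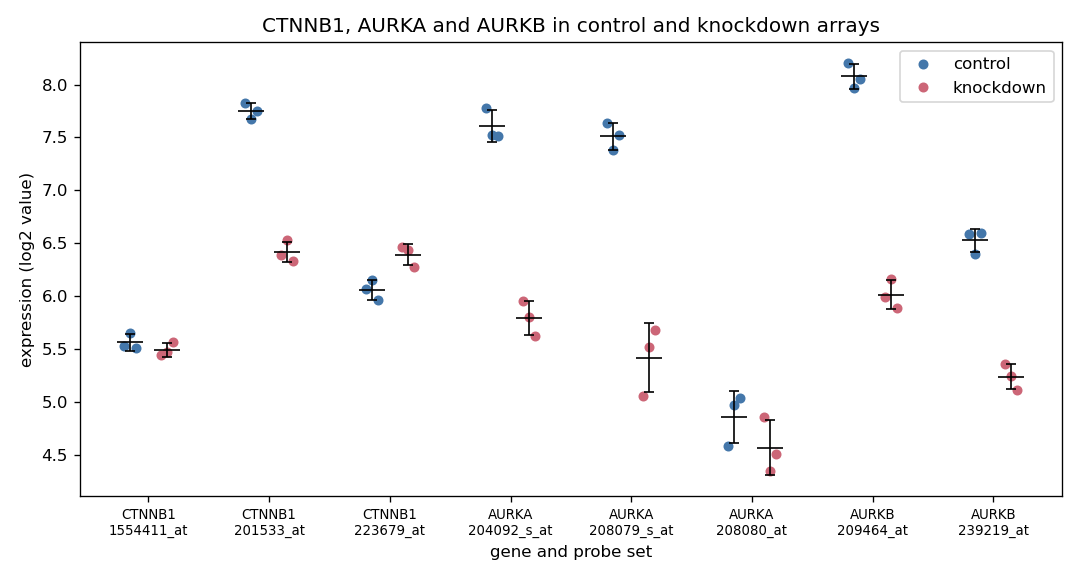
Each probe set of CTNNB1, AURKA and AURKB along the horizontal axis against its log2 value, with points for the 3 control and 3 knockdown arrays, the long bar for the mean and whiskers for the SD. The brightest probe sets fall from means of 7.75 to 6.42 (CTNNB1), 7.61 to 5.80 (AURKA) and 8.08 to 6.02 (AURKB) without overlap, while a further CTNNB1 probe set is higher by 0.33.

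The difference between the cultures was broad. Of 12939 genes tested, 6114 (47.3%) were called, 3273 higher and 2841 lower in the knockdown. Which direction held more calls was not settled: there were 2766 higher and 3316 lower after centring on array medians, 3109 and 3210 after quantile normalization, 3050 and 3264 after cyclic loess, and 2948 and 3053 without control replicate 2. Of the 6114 calls, 792 changed at least 2-fold, 354 higher and 438 lower. The groups did not overlap for 7044 genes (54.4%), where chance gives 10%. Among the called genes, 2952 had another probe set above the filter; 1709 had one called the same way and 146 one called the opposite way. Abundant genes often used for scaling also moved: GAPDH, a glycolytic enzyme, fell by 0.71 and ACTB, cytoplasmic actin, fell by 0.52, and both fell on every probe set measured and under each scaling tried for GAPDH and for the ACTB control probe sets. These 2 genes lie outside the rule for named genes.

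Of the 12 largest rises, 7 were members of the list of heat shock and immediate early genes. FOS, a subunit of the AP-1 transcription factor, lay at the table's floor of 4 in all 3 controls and at 9.27 ± 0.04 (SD, n = 3) in the knockdown, at least 38.7-fold higher (limma, adjusted p = 1.71e-25). The chemokine CCL4 rose by 4.48 (22.3-fold), DUSP1, a phosphatase of MAP kinases, by 4.47 (22.2-fold) and the transcription factor KLF4 by 3.96 (15.6-fold). ATF3 rose by 3.93, FOSB by 3.78, JUN by 3.70, CHAC1 by 3.69, TRIB1 by 3.28, ADA2 by 3.24, ASS1 by 3.07 and KLF6 by 3.04. The largest adjusted p among these 12 was that of FOSB (limma, 4.53e-19). JUN rose on 4 of its 4 probe sets, while with the mean over probe sets DUSP1 rose by 2.85 and TRIB1 by 1.97.

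Of the 12 largest falls, 6 were members of the mitosis or DNA replication lists. SPC25, a part of the NDC80 kinetochore complex, fell by 2.73 (6.63-fold), the kinetochore protein CENPW changed by −2.66, and RRM2, a subunit of ribonucleotide reductase, fell by 2.61 (6.09-fold). The cyclins CCNB1 and CCNA2 fell by 2.57 and 2.45, and MKI67, the Ki-67 proliferation antigen, fell by 2.41. UHRF1, STMN1, SLIRP, HES6, E2F8 and KIF18B fell by 2.56, 2.54, 2.54, 2.46, 2.45 and 2.43. With the mean over its probe sets, of which only 1 lay above the filter, STMN1 changed by −1.24. 

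**Figure D2:**
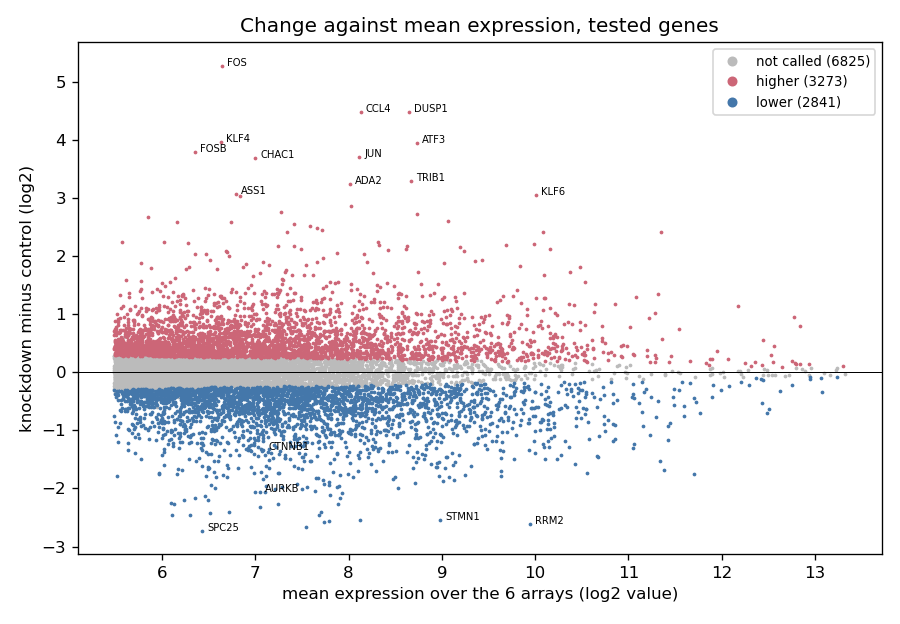
Change of each of the 12939 tested genes, knockdown minus control on the log2 scale, against its mean log2 value over the 6 arrays. The 3273 genes called higher and 2841 called lower are coloured, rises reach 5.27 at FOS, and falls reach −2.73 at SPC25.

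Across the 26 gene lists, camera at its preset correlation called 16, 10 higher and 6 lower in the knockdown. With an estimated correlation it called 0, with 5 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.168, and fry called 18. In what follows, counts adjusted over the list alone are given where they differ from those over all genes and are otherwise equal.

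Most tested genes of cell division fell. Of 52 mitosis and spindle genes tested, 51 were lower and 1 higher, with a median change of −1.67 (camera, adjusted p = 2.45e-38; adjusted p = 0.168 with an estimated correlation). The member that was higher was CCNB2, which encodes cyclin B2 and was singled out after its values were seen: the probe set with the highest mean rose by 0.34, while another bright one gave −1.43. Of 46 DNA replication and G1/S genes, 43 were lower and 0 higher, or 1 higher when adjusted over the list alone, with a median of −1.19 (camera, adjusted p = 1.39e-27; adjusted p = 0.168 with an estimated correlation). Beside RRM2 and UHRF1, thymidylate synthase TYMS fell by 1.49 and the replicative helicase subunit MCM2 changed by −1.76. Of 21 cyclins, CDKs and CDK inhibitors, 3 were higher and 6 lower, and the list was not called (median −0.04; camera, adjusted p = 0.282). Within it CDKN1A, the CDK inhibitor p21, rose by 2.10 (4.28-fold), while CDKN3 fell by 1.51 and CDK2 by 0.87. With the mean over its probe sets CDK2 changed by −0.50.

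The Wnt lists addressed whether genes tied to beta-catenin changed with it. Of 22 Wnt/beta-catenin target genes tested, 7 were higher and 2 lower, with a median of 0.10, and the list was not called (camera, adjusted p = 0.218). It was called higher by fry (adjusted p = 2.67e-04), which does not compare the list with other genes, and by camera with a filter at the 75th percentile (adjusted p = 0.0474); camera's adjusted p at the preset correlation reached 0.296 in other settings. JUN rose by 3.70, the growth factor VEGFA by 1.52 and the adhesion receptor CD44 by 0.75, while BIRC5, which encodes survivin and also acts in mitosis, fell by 1.86. JUN is also in the immediate early list and VEGFA in the hypoxia list, and the Wnt target list's mean change (0.26) exceeded its median. Of the 37 targets with a probe set, 15 lay below the filter. BIRC5 changed by −1.23 when probe sets without an _x_ or _s_ mark were preferred. Some members were chosen after their values were seen: LEF1, a DNA-binding partner of beta-catenin, fell by 0.75, AXIN2 rose by 0.38 on its brightest probe set and differed by 0.0048 on another, and DKK1 rose by 0.41. MYC differed by 0.10 and CCND1 by 0.05, neither called and both also chosen outside the rule. Of 40 Wnt pathway components, 14 were higher and 4 lower, CTNNB1 among the latter (median 0.10; camera, adjusted p = 0.249). The ligands WNT4 and WNT10A rose by 1.06 and 0.87 and the kinase CSNK1E by 0.81, but WNT4 turned to −0.27 when probe sets without an _x_ or _s_ mark were preferred, and WNT10A changed by 0.56 with the mean over its probe sets. Of 13 cadherins and catenins, 3 were higher and 4 lower, or 5 lower when adjusted over the list alone (camera, adjusted p = 0.753). CDH2 and JUP rose by 0.69 and 0.46 and PKP4 and CTNNBL1 fell by 0.47 and 0.39. PKP4 changed by −0.14 and was not called with the mean over its probe sets, and CDH2 and JUP were not called without moderation (adjusted p = 0.0529 and 0.0537). This list's median and mean were slightly above 0 (0.0023 and 0.00056) while the test's direction was lower, and the median turned to −0.06 under quantile normalization and −0.05 under centring and cyclic loess.

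**Figure D3:**
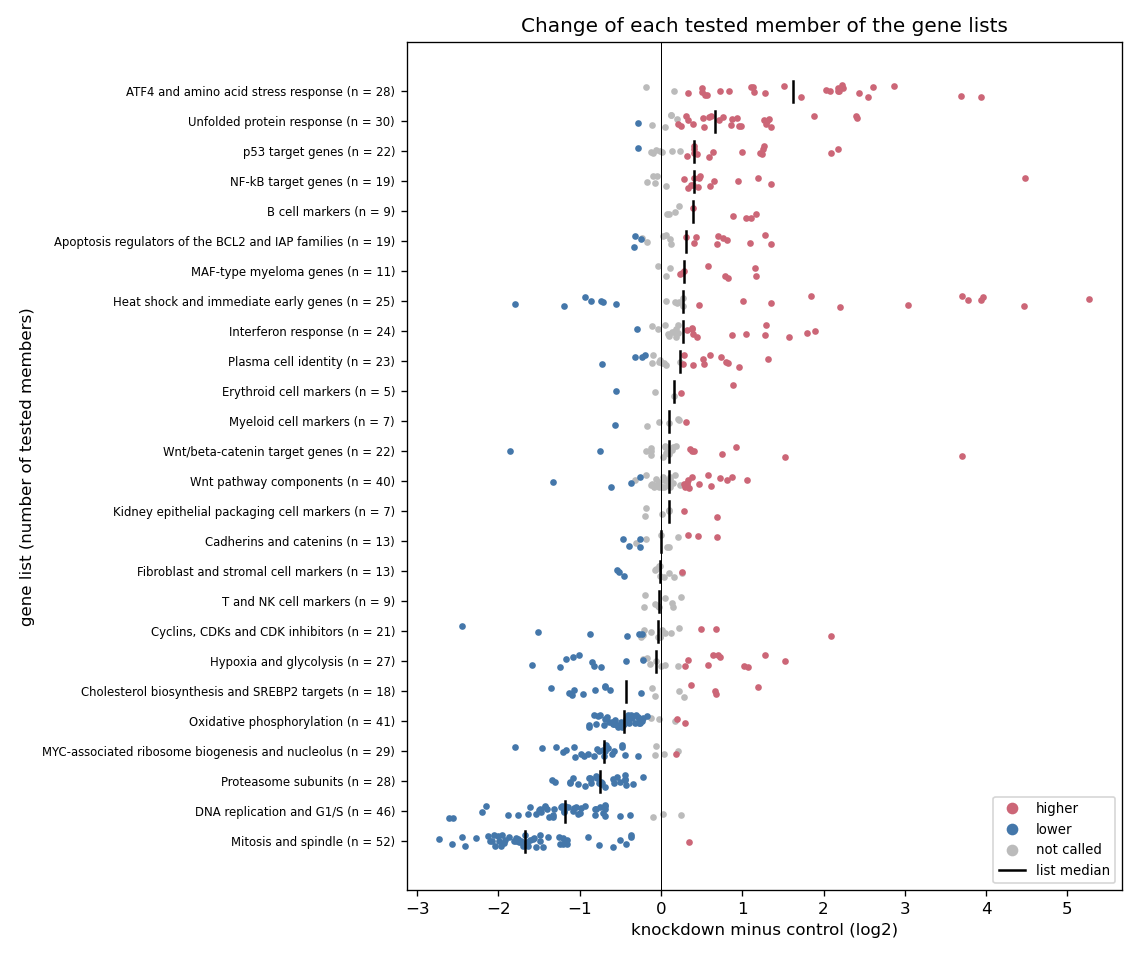
Change of each tested member of the 26 gene lists, knockdown minus control on the log2 scale, with a point per gene coloured by its call and a bar at the list's median. Mitosis (−1.67) and DNA replication (−1.19) lie lowest and ATF4 targets (1.62) highest; the cadherin list, at 0.0023, turns below 0 under the 3 other scalings.

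Most tested genes of the ATF4 and unfolded protein responses rose, while most heat shock chaperones fell. Of 28 genes of the ATF4 and amino acid stress response, 26 were higher and 0 lower, with a median of 1.62 (camera, adjusted p = 3.75e-22; adjusted p = 0.168 with an estimated correlation). ATF3 rose by 3.93, CHAC1 by 3.69, PPP1R15A, a regulatory subunit of the phosphatase of eIF2 alpha, by 2.86 and DDIT4 by 2.61. Of 30 genes of the unfolded protein response, 24 were higher and 1 lower, with a median of 0.67 (camera, adjusted p = 2.64e-12; adjusted p = 0.182 with an estimated correlation). HERPUD1 rose by 2.40, DNAJB9 by 2.41, ERN1, the sensor IRE1 alpha, by 1.88 (1.04 with the mean over its probe sets) and HSPA5, the chaperone BiP, by 1.29. The list of heat shock and immediate early genes had 12 of 25 members higher and 7 lower, or 16 higher when adjusted over the list alone (median 0.27; camera, adjusted p = 8.56e-04; adjusted p = 0.310 with an estimated correlation). A split of this list made after its values were seen gave 16 immediate early genes, 12 higher and 0 lower with a median of 2.03, and 9 heat shock chaperones, 0 higher and 7 lower with a median of −0.74. Beside these changes, the arrays' ribosomal RNA control probe sets were higher in the knockdown by 0.90 (exact permutation p = 0.1, the smallest possible), while the 3' minus 5' difference of the ACTB control probe sets was 0.67 in control and 0.58 in knockdown arrays (exact permutation p = 0.7), and that of GAPDH 0.24 and 0.28 (exact permutation p = 0.8).

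Genes of p53 and of apoptosis were on balance higher. Of 22 p53 target genes, 14 were higher and 1 lower, with a median of 0.41 (camera, adjusted p = 7.77e-05; adjusted p = 0.310 with an estimated correlation). SESN2 rose by 2.18, CDKN1A by 2.10 and TP53INP1 by 1.26 (0.41 with the mean over its probe sets), and GADD45A was 2.39-fold higher; SESN2 is also in the ATF4 list. Of 19 apoptosis regulators, 10 were higher and 3 lower (median 0.30; camera, adjusted p = 0.0209; adjusted p = 0.516 with an estimated correlation). Members of both kinds rose: the survival proteins MCL1 and BCL2 by 1.28 and 1.09 (0.59 and 0.44 with the mean over probe sets; MCL1 0.37 with probe sets without _x_ or _s_ first), and the death-promoting BH3-only proteins BCL2L11 and BMF by 1.35 (0.80 with that mean) and 0.76. The list was no longer called with other probe set rules (adjusted p = 0.0522 with the mean over probe sets and 0.215 with probe sets without _x_ or _s_ first); camera's adjusted p at the preset correlation was 0.0142 at its lowest in other settings.

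Most NF-kB target genes tested rose, as did 12 of 24 interferon response genes. Of 19 NF-kB target genes, 14 were higher and 0 lower (median 0.40; camera, adjusted p = 1.53e-04; adjusted p = 0.168 with an estimated correlation). Beside CCL4, the inhibitors TNFAIP3 and NFKBIA rose by 1.19 and 0.95 (NFKBIA by 0.50 with the mean over its probe sets) and PLEK by 1.35. Of 24 interferon response genes, 12 were higher and 1 lower (median 0.27; camera, adjusted p = 3.67e-04; adjusted p = 0.168 with an estimated correlation). ISG20 rose by 1.89, MX1 by 1.80, IRF7, a transcription factor of interferon genes, by 1.58 and OAS1 by 1.29.

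Most tested genes of the proteasome, ribosome biogenesis and oxidative phosphorylation fell. All 28 proteasome subunits tested were lower, with a median of −0.75 (camera, adjusted p = 3.06e-16; adjusted p = 0.257 with an estimated correlation). PSMB3 fell by 1.34, PSMD14 by 1.31, PSMB6 changed by −1.02 and PSMA2 fell by 0.89. Of 29 genes of MYC-associated ribosome biogenesis, 24 were lower and 1 higher, or 2 higher when adjusted over the list alone (median −0.70; camera, adjusted p = 1.02e-11; adjusted p = 0.182 with an estimated correlation). PA2G4 fell by 1.46 and the nucleolar methyltransferase FBL by 0.90. The spermidine synthase SRM fell by 1.79 and the chaperonin HSPE1 by 1.29. SRM and HSPE1 were listed as MYC-associated genes and are not factors of ribosome biogenesis. Of 41 oxidative phosphorylation genes, 36 were lower and 2 higher, or 3 higher when adjusted over the list alone (median −0.45; camera, adjusted p = 4.46e-12; adjusted p = 0.310 with an estimated correlation). COX5B, COX7B, COX6A1 and UQCRQ fell by 0.88, 0.79, 0.78 and 0.75. With the mean over its probe sets COX7B changed by −0.17 and was not called (limma, adjusted p = 0.177), but only 1 of these lay above the filter.

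Of 18 cholesterol biosynthesis genes, 10 were lower and 4 higher, or 5 higher when adjusted over the list alone (median −0.43; camera, adjusted p = 0.0205; adjusted p = 0.538 with an estimated correlation). ACAT2 fell by 1.35, HMGCS1, which makes HMG-CoA, by 1.13, IDI1 by 1.09 and EBP by 1.07; with the mean over its probe sets IDI1 changed by −0.54. Of 27 hypoxia and glycolysis genes, 10 were higher and 10 lower, and the list was not called (median −0.06; camera, adjusted p = 0.249). Fry, which does not compare the list with other genes, called it lower (adjusted p = 0.00785). Camera with the replicate number as a block also called it lower (adjusted p = 0.0136). TPI1, ALDOA, LDHA and ENO1, enzymes of glycolysis, fell by 1.58, 1.24, 1.16 and 1.01; with the mean over its probe sets ENO1 changed by −0.54. Split after the values were seen, the 13 glycolysis enzymes had 8 members lower and 2 higher (median −0.82), and the 14 others 2 lower and 8 higher (median 0.45).

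Myeloma and B-lineage genes were higher more often than lower. Of 11 MAF-type myeloma genes, 8 were higher and 0 lower (median 0.28; camera, adjusted p = 0.00104; adjusted p = 0.182 with an estimated correlation). The transcription factor MAF rose by 1.17 (2.10 when probe sets without an _x_ or _s_ mark were preferred), CX3CR1 by 1.16, RND3 by 0.83 and the integrin ITGB7 by 0.79. Of 9 B cell markers, 5 were higher and 0 lower (median 0.40; camera, adjusted p = 0.00375; adjusted p = 0.182 with an estimated correlation). CD74, the invariant chain, and HLA-DRA, a class II chain, rose by 1.17 and 0.89 (CD74 by 0.76 with the mean over its probe sets), BACH2 by 1.10 and the complement receptor CR2 by 1.05. The size for the B cell list depended on the filter: its mean change was 0.57 with it and 0.29 without it (adjusted p = 0.0460), and the control mean of BACH2 lay below the filter value. Of 23 plasma cell identity genes, 11 were higher and 4 lower (median 0.24; camera, adjusted p = 0.0433; adjusted p = 0.538 with an estimated correlation). CD28 rose by 1.32, DERL3 by 0.96, MZB1 by 0.82 and SLAMF7 by 0.80; with the mean over probe sets DERL3 rose by 0.39 and SLAMF7 by 0.51. The call on this list was lost in 5 other settings, among them centring on array medians (adjusted p = 0.0583) and leaving out control replicate 3 (adjusted p = 0.0690); camera's adjusted p at the preset correlation ran from 0.0265 to 0.151.

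Of the lists of markers of cell types besides myeloma cells, that of B cells was called higher, as given above, and the 5 others were not called. Of 9 T and NK cell markers, limma called 0, with 1 at an unadjusted p under 0.05, and the list's median (−0.02) and the test's direction were below 0 and its mean (0.0061) above (camera, adjusted p = 0.983). Of 7 myeloid markers, 1 was higher and 1 lower, or 0 higher when adjusted over the list alone (median 0.10; camera, adjusted p = 0.993); AIF1 fell by 0.57 and CSF1R rose by 0.31, the former losing its call without moderation and the latter with single arrays left out. Of 13 fibroblast markers, 3 were lower and 1 higher, or 0 higher when adjusted over the list alone (median −0.02; camera, adjusted p = 0.598): CAV1, ACTA2 and THY1 fell by 0.54, 0.51 and 0.45, and FN1 rose by 0.26. THY1 changed by −0.07 with the mean over its probe sets (adjusted p = 0.536), and it was not called without moderation either. Of 7 kidney epithelial markers, kept for cells that package virus, 2 were higher, or 1 when adjusted over the list alone (median 0.09; camera, adjusted p = 0.730), namely CDH2 (0.69) and SIX2 (0.28). Of 5 erythroid markers, 2 were higher and 1 lower (median 0.16; camera, adjusted p = 0.730), with KLF1 at 0.89, HBB at 0.24 and HBD at −0.55. HBD lost its call without moderation, and FN1, SIX2 and HBB also lost their calls when single arrays were left out; these 3 and CSF1R were not called after centring on array medians.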

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

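These signals lay outside the genes tested, in control probe sets and in probe sets with no gene symbol here, and they were looked at after the other results were known. The ribosomal RNA control probe sets were higher in all 3 knockdown arrays than in any control array, 9.92 ± 0.26 against 9.02 ± 0.54 (SD, n = 3 each), a difference of 0.90 that was 0.85 to 0.93 under the other scalings (exact permutation p = 0.1, the smallest possible). Among the 11721 probe sets with no gene symbol here, 1757 were called by limma over all non-control probe sets, 1160 of them higher and 597 lower in the knockdown. That called share was lower than the 23.2% of all non-control probe sets. The split was 1020 and 786 after quantile normalization, 945 and 873 after centring and 1034 and 837 after cyclic loess.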

How the results depend on the processing

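The added offsets and cyclic loess were chosen after seeing the data. CTNNB1 and AURKA stayed lower and called in each setting that gave a value. CTNNB1 changed by only −0.36 with the mean over its probe sets, since another of them was higher by 0.33 and a dim one differed by −0.07. Preferring probe sets without _x_ or _s_ gave AURKA no value, its only such probe set being below the filter. Without single arrays CTNNB1 changed by −1.39 to −1.29 and AURKA by −1.89 to −1.72. Called genes numbered 4433 to 6319 apart from 2825 in the test against a 1.2-fold change, which by construction asks for a larger change, and 5305 to 6001 without single arrays. No list (0) was called with an estimated correlation, where few degrees of freedom leave little power (further causes were not tested). Without single arrays 15 to 16 lists were called. Of the called lists, all but apoptosis and plasma cell identity kept their calls in the remaining settings, with a highest adjusted p of 0.0460 for B cell markers. Among lists and named genes, uncalled lists and WNT4 alone turned direction, and the cause was not tested. For lists this is the test's direction, which need not match the sign of the mean change. For T and NK markers the main mean was 0.0061, while the test's direction was lower. That direction turned to higher with fry (0.0061), without a filter (0.0398) and with the mean over probe sets (0.0581). The test's direction also turned alone for myeloid markers with the replicate block (0.0133) and erythroid markers without a filter (0.0259). For myeloid markers the mean turned with it to −0.0386 (quantile), −0.0172 (no filter) and −0.0444 (cyclic loess). For fibroblast markers the mean turned with it to 0.0213 (mean over probe sets). In some other settings the mean alone fell below 0. These included quantile normalization and centring for T and NK markers and for cadherins, and centring for myeloid markers. Without single arrays the mean ran from −0.0217 to 0.0563 for T and NK markers and from −0.0629 to 0.0534 for myeloid markers. WNT4 was −0.27 with probe sets without _x_ or _s_ first. Among single genes, 29 values lost their call in other settings and 18 without single arrays, and 1294 and 606 kept direction and call. Averaging probe sets turned the sign of 140 called genes, and preferring probe sets without _x_ or _s_ turned 212. The average took in probe sets below the filter, which can shrink a change or turn its sign. The mean made 21 of the named genes over 1.5 times smaller, and the offset of 64 made 20 smaller, dim genes such as FOS (3.38) among them, while the offset of 1 made 3 over 1.5 times larger (FOSB, BACH2 and KLF1) and 0 smaller. Same-numbered arrays deviated from their group means with r of −0.09, −0.26 and −0.30, and no array correlated best with its own number. Deviations from a mean of 3 arrays are tied to each other, so this cannot show whether the numbers pair the cultures. The replicate block gave 5494 genes, called the hypoxia and glycolysis list lower (camera, adjusted p = 0.0136) and ended the calls of CSF1R, FN1, SIX2 and HBB. The planned offsets for linear values were not run as written. Robust variances were not run for lists. Dim genes are limited by the floor: 6836 genes lay below the filter. Among genes named by the rule, FOS, KLF4, FOSB, CHAC1, ASS1, MX1, WNT4, JUP, KLF1 and BACH2 had control means below the filter value. They passed the filter only through their knockdown values. Likewise SPC25, HES6, E2F8 and KIF18B had knockdown means below it and passed only through their control values.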

Other observations

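Gene families not yet described, grouped by symbol after the data had been seen, moved in several directions; camera's adjusted p is over the 12 families, each direction held under quantile normalization, centring and cyclic loess, and the smallest adjusted p with an estimated correlation was 0.139 (HLA). Of 76 mitochondrial ribosomal proteins, 55 were lower and 4 higher (median −0.55; adjusted p = 8.70e-14), while of 57 cytosolic ribosomal proteins 18 were lower and 14 higher (median −0.04; adjusted p = 0.176); the difference between the families was not tested. All 8 chaperonin CCT subunits were lower (median −0.72; adjusted p = 8.45e-07). So were 19 of 23 nucleoporins, with 2 higher (median −0.77, camera, adjusted p = 2.71e-08). Of 21 spliceosomal SNRP and SF3 proteins, 15 were lower and 0 higher (median −0.75, camera, adjusted p = 1.09e-09). Of 19 hnRNP proteins, 14 were lower and 1 higher (median −0.40, camera, adjusted p = 7.45e-07).

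Families that were higher included the HLA genes, which present antigen, with 13 of 17 higher and 0 lower (median 0.79; adjusted p = 2.91e-07). Of 15 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include ATF4 list members, 11 were higher and 3 lower (median 0.69; adjusted p = 1.28e-04). Of 14 KLF transcription factors 10 were higher and 1 lower (median 0.60; adjusted p = 1.28e-04), and of 18 DUSP phosphatases 9 were higher and 2 lower (median 0.31; adjusted p = 0.0125). V-type ATPase subunits (9 of 19 higher, 2 lower; adjusted p = 0.0939) and ZNF proteins (72 of 302 higher, 33 lower; adjusted p = 0.203) were not called.

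In the next paragraphs, the tests of RNA degradation and heat shock, and the use of cyclic loess, were chosen after the result was seen. The rise of immediate early and ATF4 genes may have come from RNA quality or harvest rather than from the knockdown. Degraded RNA was taken to raise the 3' minus 5' difference of ACTB or GAPDH by 0.5 or more, a limit set after the values were seen. The largest excess of a knockdown array over a control array was 0.19. Degradation milder than that limit was not tested, and ribosomal RNA controls were higher by 0.90. Heat shock would raise chaperones. Of the 9 tested, 0 were higher and 7 lower, with a median change of −0.74. That fall was known before the test was chosen, so it is no independent test of heat shock. Milder RNA degradation, handling of the cultures at harvest, an off-target effect of the shRNA and an effect of the lower CTNNB1 transcript stay open, as untested.

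The fall of mitosis and replication genes could be a shift of abundant genes by the normalization or an effect of single probe sets. After cyclic loess the mitosis median was −1.69, and 0 of 10000 random lists matched on expression reached the −1.67 of the deposited values (range −0.33 to 0.31). Of 62 other probe sets of these genes above the filter, 59 (95.2%) were also lower. Both results argue against those explanations. Slower growth tied to the knockdown and a difference in culture density stay open, as untested hypotheses.

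The breadth of change, with falls of GAPDH and ACTB, might come from scaling of whole arrays. The smallest GAPDH fall under the 3 other normalizations was −0.70. Array medians already agreed within 0.1, so centring could hardly change this fall. All 3 normalizations make arrays alike as a whole and cannot show a shift in total RNA, so scaling stays open. No label gives hybridisation batches and none was tested; the knockdown itself stays open as the biological explanation, untested against other differences between the cultures. The 10 splits of the 6 arrays are too few for a share under 0.05. The real split was 1 of 10 with as many called genes (6114, highest other 0) and 1 of 10 with as many called lists (16, highest other 13). Each other split put arrays of both groups on both sides, so the difference between groups widened its spread. Those splits therefore cannot show what chance alone gives. They called 6 to 13 lists at the preset correlation with 0 called genes, so a list call can arise without any called gene.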
